A study of Mus musculus with 12 samples.

How the data were processed

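RNA was measured by sequencing in primordial germ cells sorted from 12 mouse embryos at E13.5 (embryonic day). Per the labels' protocols, the germ cells of each embryo were sorted separately, embryos were genotyped by PCR, and all embryos were on a C57BL/6 background. The labels give 4 groups, which are female conditional knockout of Ezh2 (CKO, 2 embryos), female control (Ctrl, 3 embryos), male CKO (3 embryos) and male Ctrl (4 embryos). Each library is therefore 1 embryo, and the embryo was the replicate throughout. The labels do not state the Cre driver, the genotype of the controls, the litters or the exons deleted.

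Per the labels' protocols, cDNA was made and amplified from 1 ng of total RNA with SMART-seq V4, sheared, and turned into libraries with NEBNext Ultra II. This chemistry does not mark the strand, so reads of a gene and of a gene on the opposite strand at the same place cannot be told apart. The authors deposited a table of read counts per gene for all 12 libraries, and the values used are those counts as deposited. The submitters' processing notes name CASAVA 1.8.4, Trimmomatic 0.33, TopHat2 2.0.11, featureCounts and the genome builds mm9 and NCBIM37. They do not say how reads that match several places were counted, so counts of genes in families of near-identical copies are uncertain. The table holds 37991 Ensembl gene identifiers, and 32919 of them matched a symbol, covering 99.5% of the counts. Gene names, chromosome membership, gene order, transcript length and GC content were taken from GENCODE M21 on GRCm38, a different assembly from that of the counts, so no coordinates are given.

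Total counts ran from 26180685 to 35299206 per library, and 1 CPM, the usual unit of read counts scaled to library size, corresponded to between 24.2 and 34.2 counts. Genes were kept with edgeR's filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 16708 genes. Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.926 to 1.11. A quasi-likelihood model in edgeR 4.0.16 with robust dispersion (limma 3.58.1, R 4.3.3) had a coefficient per group for all 12 libraries and 8 residual degrees of freedom. The contrasts were CKO against Ctrl in each sex, the difference between these effects, females against males among controls, and females against males among CKO embryos. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM values are computed on TMM-scaled library sizes and are given as mean ± SD over embryos.

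A group in which a gene had no count has a floor of 3 counts over the group, which is 0.032 CPM for female Ctrl, 0.0445 for female CKO, 0.0261 for male Ctrl and 0.0343 for male CKO. Folds against such a group are lower bounds. Floors cover counting error at most, since amplified reads are not independent molecules. Binomial intervals (exact Clopper-Pearson, 95%) are on shares of genes. They treat genes as independent and do not cover variation between embryos. Pairs of libraries of the same group differed by more than counting noise in every case, with a chi-square per gene between 23.6 and 95.2.

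Before the data were examined, 22 gene lists and 9 lists of cell type markers were fixed, and the genes of chromosome X formed a further list. Each list was tested in limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 32 lists of a contrast. The tests were repeated with a correlation estimated for each list and with the rotation test fry. Members called were counted over all genes tested and adjusted over the list alone. Of 719 list entries, 21 had no match in the table. Some genes are on several lists, so the results of these lists are not independent of each other. Mael, for instance, is on the methylation-linked and genome defence lists, and Sycp3 on the methylation-linked and early meiosis lists.

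The rule for the genes named in the text was fixed together with the lists. It took Ezh2, then per CKO contrast the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap in CPM, with a mean of at least 5 CPM in the higher group and an ordinary gene symbol. Sex contrasts took 8 in each direction, autosomal genes only. For each list the rule took up to 4 called members with the smallest adjusted p, and it also took Stra8, Sycp3, Dazl, Ddx4, Pou5f1, Nanog, Nanos2, Dnmt3l, Cdkn2a, Cdkn1c, Xist and Ddx3y whatever their result. A few genes that the rule selects are not reported. Any other gene that is named was chosen after its values were seen, and the text says so.

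The alternatives fixed at the same time were median-of-ratios size factors, no filter on low counts, a filter of 5 CPM in 2 libraries, only the groups compared, the replicate number as a block, limma-voom with sample quality weights, DESeq2 1.42.0, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Scaling by library size only, and removing each library's trend on transcript length or on GC content, were added after the data had been seen. So were the leave-one-out runs of the list tests, and the alternatives for the overlap of the calls and, apart from the size factors and the 5 CPM minimum, for the correlation. A fit of the male libraries with Nanos2 as a covariate was added as well. When leaving out a female CKO library leaves 1 embryo in that group, that embryo is assumed to vary like those of the other groups.

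The scripts were tested on simulated counts drawn from the means and library sizes of the 16708 tested genes, of which 16347 passed the filter again. The genes given a change had a mean of at least 1 CPM, so the shares recovered do not cover lower genes. In the simulated female CKO contrast, 55.5% of 200 genes changed by 1 on the log2 scale were recovered and 91% of 200 changed by 2, with 16 false calls. In the simulated male contrast these shares were 56% and 90% of 100 genes each, with 4 false calls. For the difference between the sexes they were 39.3% and 82.3% of 300 genes each, with 20 false calls. In the simulated female contrast camera called the list made of changed genes and 0 of 200 random lists. Simulated genes were drawn independently of each other, so this run does not test camera on lists whose genes vary together. In the data, the estimated correlation of the lists called in female CKO ran from 0.0895 for chromosome X genes to 0.506 for mitotic genes.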

Results

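Messenger RNA levels were profiled in germ cells of control and Ezh2 conditional knockout (CKO) embryos of both sexes at E13.5 (embryonic day), when female germ cells enter meiosis and male germ cells become quiescent. Ezh2 encodes the main methyltransferase of Polycomb repressive complex 2 (PRC2), which places H3K27me3. The 12 libraries, 1 per embryo, comprised 2 female CKO, 3 female Ctrl, 3 male CKO and 4 male Ctrl embryos. Total counts per library were 30892783 and 30020467 in female CKO and 31216003, 31226903 and 29172269 in female Ctrl. They were 30310801, 30237400 and 29108214 in male CKO and 35299206, 26180685, 31718918 and 27558977 in male Ctrl. Germ cell identity markers summed to between 5690 and 6460 CPM in every library. Summed markers of Sertoli cells reached 52.6 CPM in male Ctrl 1 and those of red blood cells 20.1 CPM in male CKO 1. Markers of mesonephric epithelium summed to between 231 and 613 CPM, and this list holds genes such as Krt18 and Epcam that are not restricted to that epithelium.

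The targeted gene, Ezh2 (ENSMUSG00000029687, chromosome 6), was lower in all 5 CKO libraries than in any control of the same sex. In females it fell from 154 ± 10.9 CPM (SD, n = 3) to 95.6 ± 15.7 (n = 2), a log2 fold change of -0.68 (SE 0.15, edgeR adjusted p = 0.02). In males it was at 122 ± 19.9 CPM (n = 4) in Ctrl and 84.4 ± 1.79 (n = 3) in CKO, with a log2 fold change of -0.53 (SE 0.13) that did not pass the test (edgeR adjusted p = 0.0527). The female call was lost without female CKO 1 (edgeR adjusted p = 0.165) or without female Ctrl 3 (0.0779), and the male value passed without male Ctrl 1 (0.0162), in limma-voom (0.00753), in DESeq2 (0.00777), with either other filter on low counts (0.0295 and 0.0423) and with the length or GC trend removed (0.0416 and 0.0379). These are counts over the whole gene, and the labels do not say which exons were deleted, so the remaining counts do not measure how much functional transcript was left. Ddx3y and Uty, which are Y-linked, had no counts in the 3 control females.

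In female CKO germ cells a set of X-linked and germline genes rose strongly and Pax6 fell to near 0 CPM. Nxf2, an RNA export factor gene of the germ line on the X chromosome, rose from 1.04 ± 0.00799 CPM (n = 3) to 63.4 ± 43.5 (n = 2), a log2 fold change of 5.93 (SE 0.95, edgeR adjusted p = 0.00743). Pramel3, an X-linked gene of the PRAME-like family, rose from 0.411 ± 0.417 to 16.2 ± 0.587 CPM (log2 fold change 5.31, SE 0.83). Pax6 (ENSMUSG00000027168, chromosome 2), a transcription factor of eye and brain development, fell from 17.8 ± 5.18 to 0.179 ± 0.129 CPM (log2 fold change -6.6, SE 0.56, edgeR adjusted p = 0.000134). In total 503 genes rose and 695 fell among 16708 tested in edgeR, and 394 of the rises against 113 of the falls were at least 2-fold.

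The other large rises were in Nrip3 (3.62), Nxf3 (3.54), Sqor (3.52), Xlr5c (3.36), Tro (3.29), Pla2g1b (3.28), Dpp4 (3.22) and Lpar3 (3.08), with log2 fold changes in parentheses. Nxf3 is a further X-linked RNA export factor gene, Sqor encodes a mitochondrial enzyme of sulfide oxidation, Dpp4 a cell surface peptidase and Lpar3 a receptor for lysophosphatidic acid. The other large falls included developmental transcription factors, namely Tbx1 (-2.62) of pharyngeal development and Six2 (-2.45) of kidney progenitors. Scgn, a calcium sensor gene, fell by 2.64, Hmox1, which encodes heme oxygenase, by 2.28, and Peg3, a paternally expressed imprinted zinc finger gene, by 1.67 on the log2 scale. Also lower were Tjp1 (-2.13) and Cdc42ep5 (-1.75). The edgeR adjusted p of the genes in this paragraph lay between 9e-04 in Peg3 and 0.0407 in Six2.

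Among the gene lists, multicopy X-linked germline families stood out in CKO females, with 16 of 29 tested members higher, 0 lower and a median log2 fold change of 1.21 (camera adjusted p = 1.34e-16). Adjusted over the list alone, 20 rose. Mageb4 (1.9), Usp26 (1.33), Nxf3 (3.54) and Rhox10 (2.48) had the smallest p. The list did not pass with an estimated correlation (adjusted p = 0.212). Counts of near-identical copies in the Xlr, Rhox and Mage families are uncertain. The chromosome X genes as a whole had 72 higher and 19 lower of 671, with a median of only 0.11 (camera adjusted p = 0.00503, and 0.608 with an estimated correlation). Gm364 (4.01), Mageb10-ps (2.14) and AV320801 (3.02) were the X-linked genes with the smallest p beside Mageb4.

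Germline genes known to be controlled by DNA methylation were also higher in CKO females, with 5 of 28 up, 0 down and a median of 0.49 (camera adjusted p = 1.87e-07, and 0.457 with an estimated correlation). Adjusted over the list alone, 10 rose. Tex101, a germ cell surface protein gene, went from 58.9 ± 18.9 (n = 3) to 208 ± 69.5 CPM (n = 2, log2 fold change 1.82). Mael, a piRNA pathway gene, went from 230 ± 12.1 to 532 ± 96.4 CPM (1.21), and Tuba3b, an alpha-tubulin gene with a near-identical copy, had a log2 fold change of 1.17. Of the genome defence genes 3 of 22 were higher and 1 lower (camera adjusted p = 0.00828, and 0.608 with an estimated correlation), with rises in Gtsf1 (2.45), Mael and Piwil4 (1.09) and a fall in Tdrd12 (-0.81). The genome defence list shares Mael and other genes with the methylation-linked list, so it is not separate support. Its camera call was lost without female CKO 1.

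Some early meiosis genes were higher and some pluripotency genes lower in CKO females. Of 46 early meiosis genes 4 were higher and 0 lower (camera adjusted p = 0.000197, and 0.608 with an estimated correlation), or 13 and 1 adjusted over the list alone. The synaptonemal complex genes Sycp2 and Sycp3 rose by 1.58 and 1.1, and Ccnb1ip1 and Ccdc36, which act in meiotic recombination, by 0.66 and 1.1 on the log2 scale. Stra8, which starts the meiotic programme, was at 440 ± 198 CPM in CKO against 261 ± 44.1 in Ctrl and did not pass the test (log2 fold change 0.75, SE 0.35, edgeR adjusted p = 0.227). Of 30 pluripotency genes 6 were lower and 1 higher (camera adjusted p = 7.55e-05, and 0.5 with an estimated correlation), or 11 and 1 adjusted over the list alone. Gdf3 fell by 1.19, Nanog by 1.05, Dppa3 by 0.65 and Pou5f1 by 0.56, while Klf4, named after its values were seen, was the member that rose (1.36). Female CKO 1 lay farther from the controls than female CKO 2 in several of these genes. Its Sycp3 was at 216 CPM against 102 in female CKO 2, its summed red blood cell markers were at 10.4 against 0.812 CPM, and without it neither list passed (camera adjusted p = 0.595 for early meiosis and 0.146 for pluripotency).

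In the cell cycle lists few single genes were called in CKO females. Cdkn2a, which encodes cell cycle inhibitors and is a well known Polycomb target, rose from 1.11 ± 0.31 to 4.99 ± 0.637 CPM (log2 fold change 2.17, SE 0.52, edgeR adjusted p = 0.026) and was the 1 called of 6 inhibitors, a list that was higher as a whole (camera adjusted p = 0.0156, and 0.5 with an estimated correlation). That list did not pass without female CKO 2 (camera adjusted p = 0.0513). Of 36 mitotic genes 2 were lower, Bub1 (-0.85) and Mcm7 (-0.55), and the list was lower (camera adjusted p = 0.0131, and 0.748 with an estimated correlation). It did not pass without female CKO 1 (0.788) or female Ctrl 2 (0.0625). The chromosome X list did not pass without female CKO 1 (0.458) or female Ctrl 3 (0.335).

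Developmental regulators, which are typical PRC2 targets in other cells, were not called higher as a group in CKO females. Of 12 tested Hox genes 0 were called, of 52 mesodermal and endodermal regulators 0 rose and 2 fell (Tbx1, Six2), and of 39 neural and ectodermal regulators 1 rose, Sox3 (1.29), and 4 fell, including Pax6, Irx5 (-2.34) and Lhx2 (-1.29). None of these 3 lists passed (camera adjusted p = 0.513, 0.772 and 0.307), with medians of 0.67, 0.32 and -0.13. Of 38 matched Hox genes only 12 passed the filter on low counts. The filter kept genes that reached a level of about 10 counts in at least 2 libraries. The other Hox genes did not reach it in 2 libraries, CKO or Ctrl, and changes below that level were not tested. Single members of the chromatin lists were called, and none of these lists passed in camera. Jarid2 (-0.69) and Suz12 (-0.72), PRC2 subunits like Ezh2, fell, as did the PRC1 subunits L3mbtl2 (-0.6) and Cbx7 (-0.48), the methyltransferase Dnmt1 (-0.85) and the demethylase Kdm3a (-0.76), while Zfp57, a protector of imprints listed with the DNA methylation enzymes, rose (2.41). The camera adjusted p was 0.0771 for PRC2, 0.0845 for PRC1, 0.307 for DNA methylation and TET enzymes and 0.307 for the enzymes of H3K27 and H3K9.

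Imprinted genes went both ways in CKO females, with 3 of 40 higher and 2 lower (camera adjusted p = 0.754). Meg3 (1.44) and Cd81 (0.72) rose, and Peg3 and Igf2r (-0.81) fell. Of 14 genes imprinted by H3K27me3 in early embryos, Mbnl2 rose (1.63) and Jade1 fell (-0.62), with a camera adjusted p of 0.985. Single members changed in further lists without a list call, namely Rbp4 (2), a retinol carrier gene (retinoic acid response, camera adjusted p = 0.0612), Bax (-0.77), a pro-apoptotic gene (0.772), and Ddx58 (-1.1), a sensor of viral RNA (0.907). Of 14 BMP response genes 0 were called in edgeR (camera adjusted p = 0.72). Of the male germ cell genes 2 rose and 2 fell of 27, among them Fgfr3 (-0.79), with a camera adjusted p of 0.199. Dazl, Ddx4, Cdkn1c, Dnmt3l, Nanos2 and Xist were not called, with edgeR adjusted p from 0.209 to 0.95.

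The female counts moved with the libraries used. They were 348 without female CKO 1, 317 without CKO 2, 691 without Ctrl 1, 525 without Ctrl 2 and 425 without Ctrl 3, and of the 65 called genes named for females 28, 36, 45, 43 and 34 stayed called. Those called in every run were AV320801, Dpp4, Gm364, Gtsf1, Lpar3, Mageb10-ps, Mageb4, Nxf2, Nxf3, Pax6, Peg3, Pla2g1b, Pramel3, Rhox10, Sqor, Tbx1, Tro, Usp26 and Xlr5c. Scaling by library size only, which moved the median of all genes by 0.11, gave 652 higher and 357 lower in place of 503 and 695. Rises also outnumbered falls with only the groups compared (912 and 793), in limma-voom (1126 and 942) and without female CKO 2 (178 and 139). The totals were 2068 in limma-voom and 1973 in DESeq2.

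**Figure D1:**
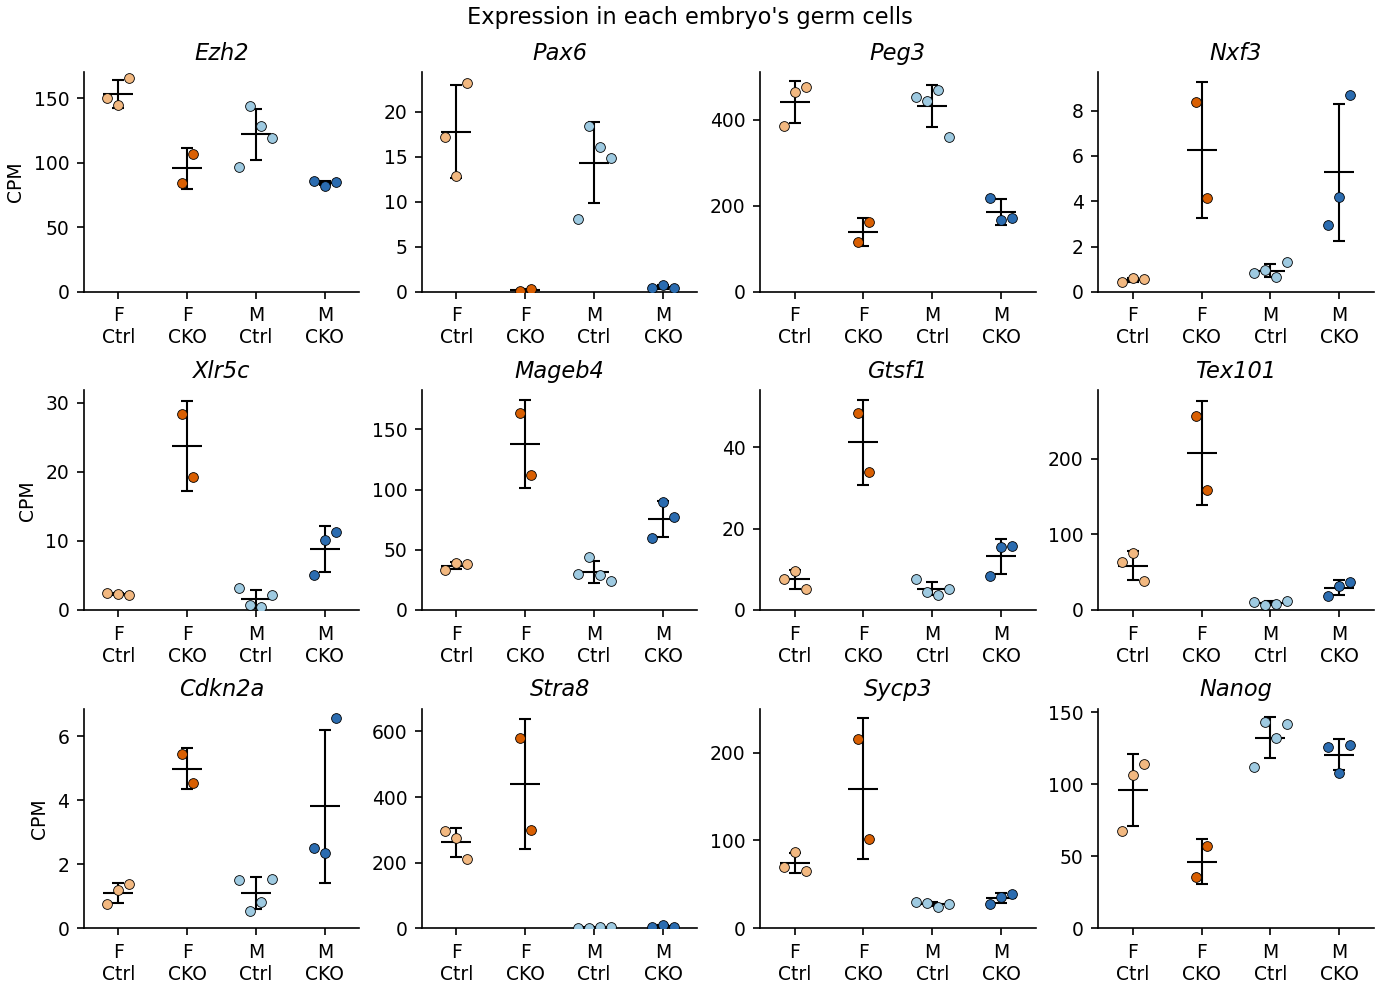
Library-size-scaled read counts (CPM, vertical axis, from 0) of 12 genes in each embryo's germ cells, for female (F) and male (M) Ctrl and CKO embryos. Each point is an embryo, the horizontal bar is the group mean and the error bar is the SD (n = 3, 2, 4 and 3 from left to right). Pax6 lies at 0.763 CPM or below in all 5 CKO embryos and at 8.03 CPM or above in all 7 controls.

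In male germ cells fewer genes passed the test than in females, and again X-linked germline genes rose while Pax6 was nearly lost. Gsto1, a glutathione transferase gene, rose from 21.2 ± 2.79 CPM (n = 4) to 92.9 ± 11.2 (n = 3), a log2 fold change of 2.13 (SE 0.15, edgeR adjusted p = 3.49e-05). Ccnd1, the gene of cyclin D1, rose from 2.96 ± 1.6 to 18.6 ± 6 CPM (log2 fold change 2.62, SE 0.35, edgeR adjusted p = 0.004). Pax6 fell from 14.3 ± 4.46 to 0.55 ± 0.184 CPM (log2 fold change -4.69, SE 0.4, edgeR adjusted p = 0.000105), and Peg3 from 431 ± 49.3 to 185 ± 29.2 CPM (-1.22, SE 0.14). In total 201 genes rose and 83 fell in edgeR, of which 117 and 21 were at least 2-fold.

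The other large rises in CKO males were in Nxf3 (2.49), Xlr5c (2.44), Chst8 (2.37), Alox15 (2.32), Xlr5a (2.27), Xlr5b (2.24), Nfib (2.11) and Fabp5 (1.98), given as log2 fold changes. Chst8 encodes a sulfotransferase, Alox15 a lipoxygenase, Nfib a transcription factor and Fabp5 a fatty acid binding protein. The other large falls were in Garem2 (-1.94), Scgn (-1.76), Plk5 (-1.4), Ano8 (-1.2), Dync2h1 (-1.08), which encodes a motor of cilia, Porcn (-1.06), needed for Wnt secretion, Aurkc (-0.97), a kinase of meiotic division, and Rassf5 (-0.89). Their edgeR adjusted p lay between 0.00167 in Chst8 and 0.0499 in Garem2.

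The multicopy X-linked families were again the list with the lowest p, with 8 of 29 members higher in CKO males, 0 lower and a median of 0.56 (camera adjusted p = 2.69e-12, and 0.229 with an estimated correlation). Adjusted over the list alone, 11 rose. Mageb4 (1.26) and Xlr3c (0.99) rose with Xlr5a and Nxf3. Across the whole X chromosome 30 of 671 genes were higher and 2 lower, with a median of 0.02 (camera adjusted p = 0.13), and Gm364 (2.81) and Mageb10-ps (1.49) were among them. Of the germline genes controlled by DNA methylation 3 of 28 rose and 0 fell (camera adjusted p = 7.23e-05, and 0.452 with an estimated correlation), namely Tex101 (1.63), Brdt (1.14), a testis bromodomain gene, and Tuba3a (0.6). The piRNA pathway genes Gtsf1 (1.31) and Piwil4 (1.02) rose, but the genome defence list did not pass (camera adjusted p = 0.185).

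Of 46 early meiosis genes 0 were called in CKO males, though the list was shifted upward by a median of 0.17 (camera adjusted p = 0.0205, and 0.804 with an estimated correlation). It did not pass without male CKO 2 (0.0847), male CKO 3 (0.082) or male Ctrl 2 (0.203). Stra8 was at 6.48 ± 2.83 CPM in CKO and 2.16 ± 1.04 in Ctrl (log2 fold change 1.58, SE 0.38, edgeR adjusted p = 0.0586), and Cdkn2a at 3.81 ± 2.39 and 1.11 ± 0.507 CPM (1.77, edgeR adjusted p = 0.0598). The pluripotency list did not pass (camera adjusted p = 0.278), nor did the lists for male germ cells (0.94), retinoic acid response (0.185), BMP response (0.856), apoptosis (0.278), cell cycle inhibitors (0.113), mitosis (0.554) or interferon (0.349). Sycp3, Dazl, Ddx4, Pou5f1, Nanog, Nanos2, Dnmt3l, Cdkn1c, Xist and Ddx3y were not called, with edgeR adjusted p between 0.111 and 0.929.

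Neural and ectodermal regulators were lower in CKO males, with 0 of 39 up and 2 down, Pax6 and Irx5 (camera adjusted p = 0.0205, and 0.452 with an estimated correlation). Irx5 was at 0.324 ± 0.186 CPM in Ctrl and 2 counts in all in CKO. The neural list did not pass without male CKO 1 (0.086), male Ctrl 2 (0.125) or male Ctrl 3 (0.0889). Of 52 mesodermal and endodermal regulators Tbx1 fell (-2.61, camera adjusted p = 0.139), and 0 of 12 Hox genes were called in edgeR (0.184). Of 40 imprinted genes Peg3 fell (camera adjusted p = 0.43), and of 14 genes imprinted by H3K27me3 none passed over all genes while 3 were higher and 1 lower adjusted over the list alone (0.653). Y-linked genes were lower as a list, with 0 of 8 called over all genes and 4 lower adjusted over the list alone (camera adjusted p = 0.000188, and 0.11 with an estimated correlation). Ddx3y was at 19.9 ± 3.54 CPM in CKO and 29.4 ± 1.67 in Ctrl. The enzymes of H3K27 and H3K9 were lower as a list with 0 of 14 called (camera adjusted p = 0.0205, and 0.452 with an estimated correlation), and did not pass without male Ctrl 1 (0.0811).

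Polycomb genes themselves changed in CKO males, with Phc2 (0.81) and Yaf2 (0.6) higher and Cbx8 (-1.84) and Ring1 (-0.84) lower, all listed as subunits of PRC1. Dnmt3b, a DNA methyltransferase gene, rose (0.92, list camera adjusted p = 0.856). Krt18 rose in CKO males (1.14) and CKO females (1.01), and the mesonephric epithelium markers to which it belongs were higher as a list in males (camera adjusted p = 0.0205, and 0.313 with an estimated correlation). Lhx1 of the same list fell in females (-1.41). Egfl7, an endothelial marker, rose in males (0.89), with an endothelial list that did not pass (camera adjusted p = 0.17). The PRC1 list had 3 members higher and 3 lower (camera adjusted p = 0.596), and the PRC2 list 0 called (0.173).

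The male counts depended on the libraries. They were 36 without male CKO 2, 48 without CKO 3, 502 without Ctrl 2, 85 without Ctrl 3 and 151 without Ctrl 4. Without male CKO 1 there were 145 rises and 136 falls in place of 201 and 83. Of the 38 called genes named for males 11, 12, 37, 16 and 26 stayed called without CKO 2, CKO 3, Ctrl 2, Ctrl 3 and Ctrl 4, and 28 without CKO 1. Those called in every run were Ccnd1, Chst8, Gm364, Gsto1, Mageb10-ps, Pax6, Peg3, Tbx1 and Xlr5a. A fit of the 7 male libraries alone called 63 genes, and 1039 with Nanos2 as a covariate. The replicate number as a block left 105 (with 23 of the 38 named genes), and limma-voom and DESeq2 called 1122 and 982. The lower number of calls in males than in females therefore does not by itself show a weaker response.

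**Figure D2:**
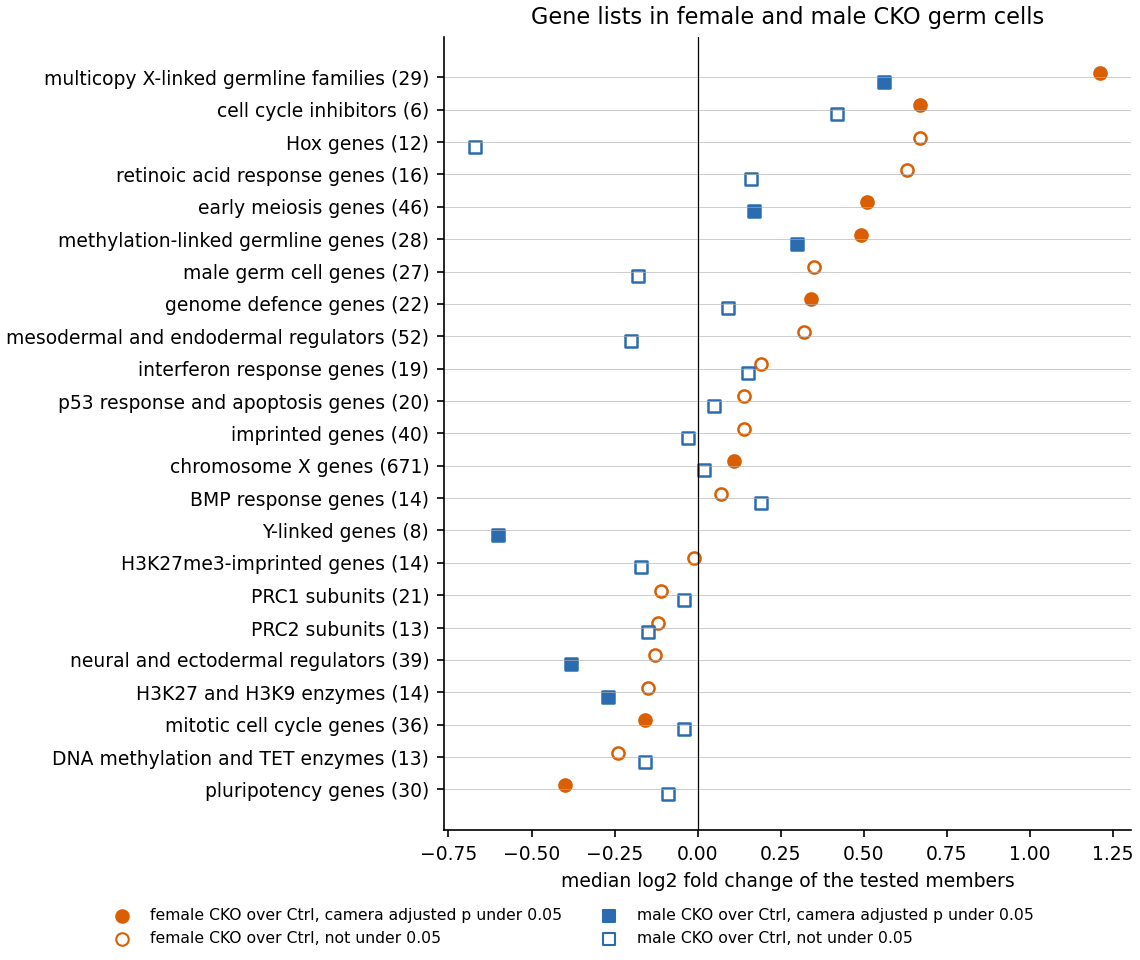
Median log2 fold change (horizontal axis) of the tested members of each gene list in CKO over Ctrl, in females (circles) and males (squares), with the number of tested members in parentheses. Filled symbols have a camera adjusted p under 0.05 with the preset correlation, genes with no count in a group are set to their bound, and Y-linked genes are drawn for males only. Among the lists drawn, which leave out the cell type markers, the multicopy X-linked families lie farthest to the right in both sexes, at 1.21 and 0.56.

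The CKO effects of the sexes were compared to ask which genes respond to Ezh2 in both. Pax6, Peg3, Scgn, Tbx1 and Irx5 fell in both sexes, and Nxf3, Xlr5a, Xlr5b, Xlr5c, Mageb4, Tex101, Gtsf1 and Piwil4 rose in both. In all, 105 genes were higher in both and 44 lower in both, against 6.05 and 3.45 if the calls were independent (Fisher's exact test, two-sided, p = 3.06e-107 and 7.26e-39), and 0 genes were called in opposite directions (1 in DESeq2 and 1 without female CKO 1). The contrasts share no library, but both come from 1 fit with a shared dispersion per gene. Fisher's test also treats genes as independent, so its p-values do not measure how well the overlap repeats across embryos. Of the 201 male rises 195 had the same sign in females, as had 76 of the 83 male falls. Across the 16708 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.38 and a Spearman rho of 0.42, and over 10242 genes with a mean of at least 5 CPM both were 0.53. The Pearson r was 0.15 with no filter on low counts and 0.26 to 0.41 without a library. The number higher in both was 37 without female CKO 1, 58 without female CKO 2, 19 without male CKO 2, 28 without male CKO 3, 60 and 62 without female Ctrl 2 and 3, 45 and 63 without male Ctrl 3 and 4, and the number lower in both ranged from 5 to 78 over the left-out libraries. With the replicate number as a block 42 were higher and 17 lower in both, with only the groups compared 43 and 7, in limma-voom 299 and 195, and in DESeq2 283 and 157.

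**Figure D3:**
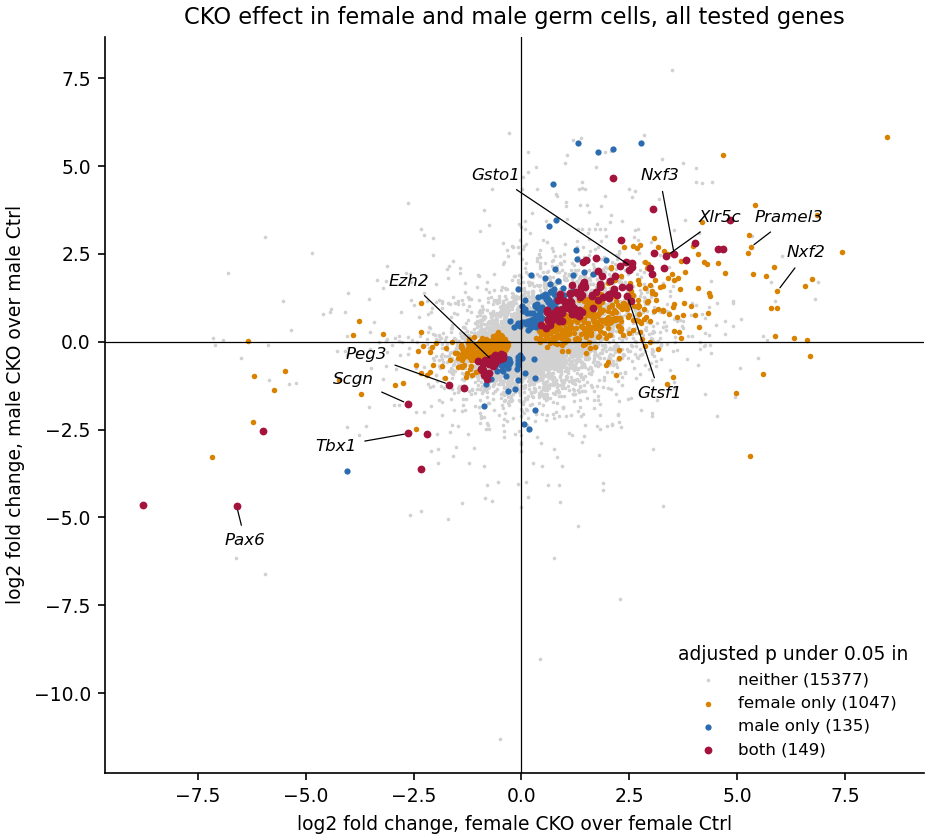
Log2 fold change of CKO over Ctrl in females (horizontal axis) and in males (vertical axis) for each of the 16708 tested genes, coloured by the sex in which the edgeR adjusted p was under 0.05. The 105 genes called higher and the 44 called lower in both sexes (red) lie at the upper right and the lower left, with Pax6 at -6.6 and -4.69. Folds of genes with no count in a group are fitted values and not bounds.

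No gene passed the test of a difference between the female and male CKO effects in edgeR, with 1401 of 16708 genes at an unadjusted p under 0.05, 51 called by DESeq2 and 0 by limma-voom. Nanog had a CKO effect of -1.05 in females and -0.13 in males, with a difference of -0.92 (SE 0.29, edgeR adjusted p = 0.493). As lists, the multicopy X-linked families (camera adjusted p = 0.000798), pluripotency genes (0.000798) and methylation-linked germline genes (0.0375) differed between the sexes, with medians of the difference of 0.6, -0.24 and 0.26. With an estimated correlation the adjusted p was 0.675 for all 3. The 3 lists did not pass without female CKO 1 (camera adjusted p = 0.629, 0.629 and 0.834), and without it 3 genes were called. The methylation-linked list also did not pass without female Ctrl 3 (0.17), male CKO 1 (0.205), male Ctrl 1 (0.167) or male Ctrl 4 (0.0755).

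Control females and control males were compared as the background for the CKO effects. Stra8 was at 261 ± 44.1 CPM in females (n = 3) and 2.16 ± 1.04 in males (n = 4), a log2 fold change of 6.91 (SE 0.39, edgeR adjusted p = 2.01e-07). Lefty2, a Nodal pathway gene, was at 0.793 ± 0.364 CPM in females and 618 ± 176 in males (-9.6, SE 0.34). In total 3358 genes were higher in females and 3246 lower. Scaling by library size only gave 4062 and 2592, with a shift of all genes by 0.1.

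Other genes much higher in control females were Cdx2 (6.99) and Hand1 (6.58), developmental transcription factors, Dlx3 (6.87), Phlda2 (6.56), Sct (6.53), Trmt9b (6.16) and Pwwp2b (5.66), as log2 fold changes. Higher in males were Tdgf1 (-8.07) and Lefty1 (-7.57) of the Nodal pathway and Hesx1 (-6.55). Krt17 had no counts in females and ranged from 0.536 to 16.4 CPM among the control males. Nanos2, the determinant of male germ cell fate, was at 10.9 ± 11.2 CPM in males against 2 counts in all in females, and ranged from 0.33 to 23.8 CPM among the 4 control males.

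Meiosis and BMP response genes separated the control sexes as lists. Of 46 early meiosis genes 35 were higher in females and 2 lower, with Zglp1 (2.01), M1ap (2.78) and Meioc (3.99) next to Stra8 (camera adjusted p = 1.57e-11, and 0.285 with an estimated correlation). Of 14 BMP response genes 12 were higher and 1 lower, among them Id1 (4.63), Id2 (3.3) and Msx1 (4.88), and this list held with an estimated correlation (camera adjusted p = 7.93e-20, and 0.000806). Male germ cell genes were lower in females (11 of 27 down, 3 up, camera adjusted p = 5.43e-06, and 0.215 with an estimated correlation), although Fgfr3 was higher (3.07). Pluripotency genes were lower (14 of 30 down, 3 up, camera adjusted p = 0.0056, and 0.483 with an estimated correlation), including Dppa3 (-0.97) and Tcl1 (-1.22), but Alpl was higher (1.63). Genes of the X chromosome were higher in females (243 of 671 up, 48 down, median 0.41, camera adjusted p = 6.97e-05, and 0.483 with an estimated correlation), for instance Cited1 (3.33), Clcn5 (2.15) and Porcn (3.35).

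Further lists differed between control females and males. Neural and ectodermal regulators were higher in females (16 of 39 up, 5 down, camera adjusted p = 0.000263, and 0.215 with an estimated correlation), with Msx2 (4.98) and Lhx2 (3.29). Methylation-linked germline genes were higher (11 of 28 up, 0 down, camera adjusted p = 0.0115, and 0.532 with an estimated correlation), with Hormad1 (0.81) and Cyct (0.72). Imprinted genes were higher (14 of 40 up, 6 down, camera adjusted p = 0.0483, and 0.215 with an estimated correlation), with Slc22a18 (5.09) and Plagl1 (3.93), but Mest was lower (-2.55). That call was lost without female Ctrl 1 (0.053) or male Ctrl 3 (0.063). Interferon response genes were lower (5 of 19 down, 0 up, camera adjusted p = 0.0124, and 0.505 with an estimated correlation), with Irgm1 (-4.51) and Ifi27 (-1.78). All 8 Y-linked genes were lower (camera adjusted p = 7.12e-44, and 3.77e-05 with an estimated correlation), Ddx3y by at least 917-fold and Uty by at least 1060-fold. Sertoli cell markers were lower (6 of 9 down, 1 up, camera adjusted p = 0.0115, and 0.483 with an estimated correlation), including Sox9 (-5.05), at 3.34 ± 1.82 CPM in males, and Cst9 and Amh, which had no counts in females and ranged from 2.75 to 8.58 and from 1.02 to 5.34 CPM in males, highest in male Ctrl 1.

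Lists without a call between the control sexes (camera adjusted p from 0.0678 for PRC1 to 0.936 for cell cycle inhibitors) held large single differences. They included Phf19 (2.63), a PRC2 subunit, Phc1 (-1.55) and Cbx8 (2.99) of PRC1, Gata2 (4.68), Gata3 (4.19) and Wnt3 (-3.7) among mesodermal regulators, and Rarb (4.63) and Crabp2 (2.47) among retinoic acid response genes. Also different were Tet1 (-1.25), Pmaip1 (-6.5), an apoptosis gene, Aurkb (-1.09), Tdrd5 (-1.21), Slc38a4 (2.32), Xlr (2.45), Cdkn1b (-1.14) and Cdkn1c (1.21). Ezh2 itself was higher in females (0.33, SE 0.12, edgeR adjusted p = 0.0492), a call that held only without male Ctrl 2 (0.0129) among the runs leaving out a library (0.0575 to 0.146 in the others). It was also lost with the replicate number as a block (0.0618), with only the groups compared (0.0682) and with the GC trend removed (0.24, edgeR adjusted p = 0.125). Also higher in females were Sycp3 (1.44) and Dazl (0.37), while Pou5f1 was lower (-0.44). Ddx4, Nanog, Dnmt3l, Cdkn2a and Xist were not called, with edgeR adjusted p between 0.0622 and 0.991.

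CKO females and CKO males differed by sex in a similar number of genes as the controls did, and in many of the same marker genes. Phlda2 was at 349 ± 41.5 CPM in CKO females (n = 2) and 2.37 ± 0.471 in CKO males (n = 3), a log2 fold change of 7.19 (SE 0.9, edgeR adjusted p = 0.000249). Stra8 was at 440 ± 198 and 6.48 ± 2.83 CPM (6.09), and Lefty2 at 0.402 ± 0.113 and 748 ± 46.9 CPM (-10.85). Higher in CKO females were also Cdx2 (6.92), Dlx3 (6.86), Dmrtb1 (6.79), H2-Ab1 (6.71), Hand1 (6.65), Sct (6.62) and Alpk3 (6.48). Higher in CKO males were Lefty1 (-8.19), Ctsw (-8.12), Hesx1 (-7.49) and Cst9, at least 125-fold, as well as Otx2, which had 1 count in CKO females and 13.7 ± 3.02 CPM in CKO males. In total 3239 genes were higher in females and 3172 lower, or 4336 and 2212 scaled by library size only, with a shift of all genes by 0.21. Without female CKO 1 the total was 4063 in place of 6411.

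Since H3K27me3 marks silent genes, the calls were split by their level in controls. Of the 503 genes that rose in CKO females 153 (30.4%, 95% interval 26.4 to 34.6%) had a control mean under 1 CPM, against 23.4% of all tested genes. Of the 695 that fell 16 (2.3%) did. In males 31 of 201 rises (15.4%, 10.7 to 21.2%) were near silent in controls, against 24.8% of all tested genes, and 3 of 83 falls (3.61%). Genes near the floor leave little room for a test downward. The same control means enter the fold changes, so the shares among the rises are not an independent test either. Pramel3, Nrip3, Nxf3, Sqor, Pla2g1b and Zfp57 were among the near silent genes that rose in females, with control means from 0.411 to 0.746 CPM.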

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

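All tests of explanations in this part were chosen after the results they address had been seen, and the genes checked for a library apart from its group were enlarged after a smaller set had been examined. Only male Ctrl, with 4 embryos, is large enough for a check of a single embryo against its group. Of 165 values checked there 10 stood apart, where chance gives about 1 in 20.

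In male Ctrl 1 the summed Sertoli cell markers were at 52.6 CPM, and Ptgds and Sox9, members of that list, at 6.01 and 6.04 CPM. Dnmt3l was at 0.701 CPM in male Ctrl 1. In male Ctrl 2 the summed germ cell identity markers were at 5690 CPM. Also apart in male Ctrl 2 were Porcn (19 CPM), Hand1 (0.743 CPM), Phlda2 (9.45 CPM), Msx2 (6.81 CPM) and Etv6 (50.7 CPM).

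The effect of the CKO differed between females and males in the test of that difference for the multicopy X-linked families (camera adjusted p = 0.000798), pluripotency genes (0.000798) and methylation-linked germline genes (0.0375). With an estimated correlation each adjusted p was 0.675, and without female CKO 1 none passed (0.629, 0.629 and 0.834).

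The multicopy X-linked families were higher in CKO germ cells of both sexes, and reads shared between near-identical copies might produce rises in some copies at the expense of others. Against this for the Xlr genes, the summed Xlr counts rose by 1.11 in females (pooled SD 0.33) and 0.73 in males (0.17). Members called higher held 84% and 40.5% of these sums in CKO. The Rhox sums changed by -0.44 (pooled SD 0.19) in females and 0.24 (SD 0.74) in males. The Mage sums changed by 0.01 (SD 0.25) and -0.08 (SD 0.15). The male Rhox change and the Mage changes were smaller than their SD, as offsetting copies would leave them. The Rhox and Mage sums could still not decide, as members called higher hold at most 6.71% and 12.9% of them. A shift of the whole X chromosome by as much as the list is argued against by the 642 other tested X-linked genes. Their median was 0.1 in females and 0 in males, against 1.21 and 0.56 for the list and -0.01 and -0.02 for autosomal genes. Single X-linked genes spread widely (interquartile range 1.13 and 0.67), so a smaller shift, or one of part of these genes, stays open. A later stage of the CKO males stays open, because Nanos2, used as a covariate for stage, shares only 4.57% of its variance with the genotype, so that the list median of 0.69 with it against 0.56 without it cannot decide. A release of these genes by the Ezh2 CKO, the difference the design names, also stays open, and the data hold no measurement of H3K27me3 with which to test it.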

How the results depend on the processing

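The runs with library size only, with the length or GC trend removed, with Nanos2 as a covariate and the list tests without a library were chosen after seeing the data, as were most alternatives for the correlation. Where no cause is given below, the cause was not tested. None of the called genes that the naming rule selects changed direction in its contrast in the runs made, nor did a called list. The number of genes changed in female CKO was 1198, against 2068 in limma-voom, 1973 in DESeq2, 507 with an absolute log2 fold change of at least 1 and 317 to 691 without a library, where fewer samples were fitted. In male CKO it was 284, against 105 with the replicate number as a block, 63 with only the groups compared, 1122 in limma-voom and 982 in DESeq2. The male count was 138 with the minimum fold change and 36 to 502 without a library. In the fit of the male libraries alone it went from 63 to 1039 with Nanos2 as a covariate. Replicate numbers in the titles gave no clear sign of pairing, as profiles with the same number had an r between 0 and 0.23. The deposited columns number the females differently, and only CKO 2 and Ctrl 2 share a number there (r = 0.03). For the difference between the sexes the count was 0, against 2 with no filter, 51 in DESeq2 and 0 to 3 without a library, and it has no value with only the groups compared, since it needs all groups. The minimum fold change left 3088 of 6604 genes between the control sexes and 3342 of 6411 between the CKO sexes, and the latter count was 4063 to 5602 without a library.

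With an estimated correlation the lists called went from 8 to 0 in female CKO, 7 to 0 in male CKO, 3 to 0 for the difference and 11 to 2 between the control sexes. With fry, which asks another question, they were 4, 3, 0 and 20, but not always the same lists. Of the camera calls fry kept 1 of 8 in female CKO and 3 of 7 in male CKO. It kept 0 of 3 for the difference and 11 of 11 between the control sexes. The other female calls by fry were PRC2 subunits (lower), retinoic acid response genes and endothelial markers (both higher). The PRC2 list includes the targeted gene Ezh2, and it was not tested without Ezh2. Each of these lists had a fry adjusted p of 0.0271, and camera did not call them. Male lists fell to 4 with the length trend removed, where early meiosis (0.0777), the enzymes of H3K27 and H3K9 (0.0859) and mesonephric markers (0.0717) did not pass. The difference had 5 lists with the filter of 5 CPM. Without a library the female lists numbered 4 to 9 and those of the difference 0 to 9. Further camera calls were lost for chromosome X in females with no filter (adjusted p = 0.114), for mitotic genes in females with the 5 CPM filter (0.15), and for neural regulators in males with either filter (0.087 and 0.146). They were also lost for mesonephric markers in males with the 5 CPM filter (0.0599), methylation-linked genes in the difference with no filter (0.0717) or the block (0.183), and interferon genes between control sexes with the block (0.0526). Imprinted genes between control sexes did not pass with the 5 CPM filter (0.0868), only the groups compared (0.0524), library size only (0.0614) or the length trend removed (0.0556).

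The correlation of the female and male effects was 0.38, against 0.53 over genes of at least 5 CPM, 0.15 with no filter, 0.55 with the 5 CPM filter, 0.42 in limma-voom and 0.26 to 0.41 without a library. Near silent genes were 30.4% of the female rises at a limit of 1 CPM, 21.9% at 0.5 and 43.9% at 2 CPM, and in males 15.4%, 9.95% and 24.9%.

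Uncalled genes changed sign without a library. The ranges were -0.34 to 0.81 for Dnmt3l and -0.81 to 1.66 for Xist in females, and -0.02 to 0.18 for Ddx4, -0.71 to 0.42 for Nanos2, -0.16 to 0.41 for Cdkn1c and -0.91 to 0.11 for Xist in males. Between control sexes they were -0.04 to 0.15 for Ddx4, -2.02 to 0.96 for Dnmt3l and -0.23 to 0.2 for Cdkn2a. Nanos2 in males was 1.06 with the block and 1.13 in limma-voom, and Xist was 0.06 with the block. Between control sexes Ddx4 was -0.05 with the GC trend removed, and Cdkn2a was 0.2 with the block, 0.08 with library size only, 0.1 with the GC trend removed and 0.19 in limma-voom.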

Other observations

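The tests of explanations in this part were chosen after the results had been seen, except for the splits of the samples, which were fixed beforehand. The test of the genes around Pax6 was reworded after its values had been seen, and the length tests were repeated after a first version with another centring.

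Markers of other cell types were checked in the sorted germ cells. Over 57 measured somatic markers the median log2 fold change in CKO was 0.37 in females and 0.26 in males. Red blood cell markers were at 10.4 CPM in female CKO 1 and 20.1 CPM in male CKO 1 and at 1.34 CPM or less in the other libraries, with camera adjusted p of 0.111 and 0.159. The lists for pre-granulosa (0.72 and 0.856), Sertoli (0.985 and 0.964), steroidogenic (0.985 and 0.993), stroma (0.0845 and 0.43), endothelial (0.0907 and 0.17) and leukocyte markers (0.72 and 0.94) did not pass in females and males by the camera adjusted p, nor did germ cell identity markers (0.307 and 0.964).

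Pax6 was lower in the CKO of both sexes, at -6.6 in females and -4.69 in males. A loss over several neighbouring genes may be set against the 10 nearest tested genes in the GRCm38 annotation, whose lowest log2 fold change was -0.45. As first worded, with a change of more than 1 in either direction, that test was undecided, since Prrg4 (1.01, edgeR adjusted p = 0.369) and Ccdc73 (1.03, 0.0124) were higher in females. A general loss of gonadal somatic cells from CKO sorts is argued against by the somatic marker medians, the lower of which was 0.26. The medians pool 57 markers of several cell types, so they cannot show the loss of a single type, which stays open. In females 32 markers were above 0 and 4 below -2, and in males 35 and 2. Leukocyte markers had a median of -1.35 in females and 0.71 in males. The female value rested on female Ctrl 2, where these markers summed to 10.8 CPM. They summed to 1.97 and 2.61 CPM in female Ctrl 1 and 3 and to 2.31 and 3.1 CPM in female CKO 1 and 2. Pax6 was at 12.9 CPM in female Ctrl 2 and at 17.2 and 23.2 CPM in female Ctrl 1 and 3. Among the control females it therefore did not follow the leukocyte markers. A response of Pax6 to Ezh2, direct or indirect, and a difference in genotype linked to the floxed or Cre alleles stay open and were not tested.

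Genes that fell in CKO had long transcripts in the GRCm38 annotation, with a median of 4383.5 bases in females and 4595 in males against 3149 for all tested genes. A trend of the libraries with transcript length may contribute. For genes with a mean log2 CPM above 3, each library's deviation from the gene's mean over all 12 libraries was compared with transcript length. The rank correlation was -0.223 and -0.313 in male CKO 2 and 3. It was -0.0162 in male CKO 1 and between -0.0934 and 0.138 in male Ctrl. In females it was -0.0502 and -0.0242 in CKO and between 0.0579 and 0.232 in Ctrl. With that trend removed the median was 3774 in females, above the range of random gene sets (2983 to 3328), and 615 of the 695 genes remained called. In males it was 3485, within the range of random sets (2595 to 3738), so the trend could account for the male pattern, and 61 of the 83 genes remained called. No biological explanation was tested.

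Other groupings of the same libraries were fitted to ask whether other splits give as many calls. For the male CKO, 1 of 35 splits of the 7 male libraries, the real one with 284 genes, gave as many calls, and the highest other gave 68. For the control sexes it was 1 of 35 as well, with 6604 genes against 2560. The real split gave the most calls in both comparisons. That is the strongest outcome that 35 splits can give, and it does not exclude chance. The female CKO group of 2 is too small for such splits.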
